A study of Mus musculus with 4 samples.

How the data were processed

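Total RNA from 4 samples of Beta-TC-6 cells was measured on Affymetrix Mouse Gene 2.1 ST arrays, 1 array per sample. Beta-TC-6 is a mouse pancreatic beta cell line. Per the labels' protocols, the cells were transfected by a lipid reagent either with a pool of RNA duplexes against NF45 (siNF45, 2 samples) or with a negative control siRNA (siNTC, 2 samples), RNA was extracted with a miRNeasy kit, and labelled single-stranded DNA was made from total RNA with the WT PLUS kit. The labels do not say whether the 2 samples of a group came from separate transfections, so the p-values measure only the spread between these samples, which may be technical.

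The deposited table holds 1 log2 expression value per probe set and array, made by the authors. Per the submitters' processing notes, Transcriptome Analysis Console was used. Its version, the summarisation algorithm and any background correction are not given in the sources used here. The log base was not stated either. Values ran from 0.12 to 12.21 with 2 decimals, the range usual for log2 values of this kind of array, and were taken as log2. All folds rest on that base. The table names the columns by sample, gives genes uncentred, and has array medians of 1.64, 1.64, 1.66 and 1.66, so direction is fixed by the sample labels while the software version, the algorithm, any background correction and the base remain unknown. No detection call and no probe-level intensity was used here, and the precision of a value is limited by the number of arrays.

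Of 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several symbols and 16010 were unnamed here. Gene symbols were checked by gene number against a RefSeq gene table of the mouse assembly GRCm38.p6, which held 23328 of the 23521, and no symbol needed updating. Only probe sets with 1 symbol were tested. A probe set had to reach a mean over all 4 arrays of at least the median of all probe sets, which was 1.65, and for a gene with several such probe sets the brightest was kept. This left 11742 genes. Some members of the gene lists are not reported here.

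Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), on the values as deposited, with Benjamini-Hochberg adjustment over the 11742 genes and a threshold of 0.05. Differences are siNF45 minus siNTC on the log2 scale, with the moderated standard error (SE). Values per group are means ± SD over 2 arrays. The fit had 2 residual degrees of freedom and a prior of 3.69. For Ilf2 alone an exact permutation test was added, which cannot go below a two-sided p of 0.333 with 2 arrays against 2.

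The design, the alternatives, the rule for named genes and 19 gene lists were fixed before the data were examined. Each list was tested with camera, at the preset inter-gene correlation of 0.01, against all other tested genes, with adjustment over the 18 lists that had at least 5 measured members. Counts of list members are given after adjustment over all genes and, separately, adjusted over the list alone. Ilf2 was always named. For each direction the rule named the 15 genes with the largest change among those that passed with both siNF45 arrays on the same side of both siNTC arrays, or, where fewer than 10 passed, the 10 genes with the smallest p, leaving out models without a proper name. It also named the 4 members of each list with the smallest p. Histones, ribosomal proteins, microRNA genes and small nucleolar RNAs were collected by symbol prefix, which also took in a few relatives such as H1f10 and Rps19bp1.

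The script was tested on simulated data for this comparison, with 11742 genes, 200 of them changed, in 20 runs. It recovered 96.8% of genes changed by 2 on the log2 scale and 56.0% of those changed by 1 at the adjusted threshold, with 5.30% false calls among all calls. A list of 24 genes shifted by 0.35 was found in 20 of 20 runs, and an unshifted list in 0 of 20. The simulated genes were independent of each other, which real members of a list are not.

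Alternatives were no filter, a filter at the 70th percentile, quantile normalization, arrays centred on their median over the tested genes, eBayes with a trend or robust, the replicate number as a block, the mean of all probe sets of a gene, leaving out each array, other thresholds, an unmoderated per-gene test, camera with an estimated correlation, and fry. The replicate numbers 1 and 2 occur in both groups and were not taken to pair the samples. No batch, date or slide was used here.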

Results

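Expression was profiled in 4 samples of the mouse beta cell line Beta-TC-6, 2 transfected with a control siRNA (siNTC) and 2 depleted of NF45 by RNA interference (siNF45). NF45 is encoded by Ilf2 and is part of a complex that binds double-stranded RNA. The 4 arrays had similar distributions, slightly narrower on the siNF45 arrays. Upper quartiles were 3.36 and 3.31 for the siNTC arrays and 3.29 and 3.2 for the siNF45 arrays on the log2 scale. Lower quartiles were 1.17 and 1.2 for siNTC and 1.22 and 1.24 for siNF45. Replicates differed by a median of 0.15 in both groups. Across probe sets, which are not independent replicates, the siNTC replicates correlated at 0.982 and the siNF45 replicates at 0.975, and pairs of arrays from different groups correlated at 0.970 to 0.979. The comparison asked which transcripts depend on NF45 in this beta cell line.

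The knockdown was seen in the target itself. Ilf2 read 5.79 and 5.98 on the siNTC arrays and 3.67 and 3.77 on the siNF45 arrays. It fell from 5.89 ± 0.13 in siNTC to 3.72 ± 0.07 in siNF45 (log2, SD, n = 2 each), a difference of -2.17 (SE 0.13) or 4.48-fold, with a limma adjusted p of 0.020. The exact permutation p was 0.333, the smallest that 2 arrays against 2 allow. Among proteins known to work with the complex, the RNA helicase Dhx9 differed by -0.49 (SE 0.13) and the RNA editing enzyme Adar by -0.37 (SE 0.13), and neither passed (limma adjusted p = 0.157 and 0.245). Strbp, a double-stranded RNA-binding protein, differed by 0.16 (SE 0.12).

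Besides Ilf2, 8 genes fell and 1 gene rose upon NF45 depletion. Kcnq3, a potassium channel subunit, fell 4.52-fold, from 4.63 ± 0.12 to 2.45 ± 0.08 (SD, n = 2). Cdh11, a cadherin of cell adhesion, fell 4.42-fold and Nexmif 3.94-fold. Reln, the secreted glycoprotein reelin, fell 3.66-fold, the neuropeptide galanin (Gal) 3.53-fold, and Gad2, the GABA-synthesising enzyme known as an islet autoantigen, 3.03-fold. The other 2 were histone genes, H2bc12, which fell 2.89-fold, and H2ac1, which fell 2.72-fold. Trp53inp1, a p53-induced nuclear protein, was the gene that rose, from 3.97 ± 0.07 to 5.47 ± 0.04 or 2.83-fold. The limma adjusted p of these 9 genes lay between 0.020 for Nexmif and Kcnq3 and 0.0498 for H2ac1. These 10 genes kept their direction in every alternative that was run. They were called in the fit as designed, and none was called in the 4 fits that left out 1 array, where the smallest limma adjusted p was 0.307 and 1236 to 1670 genes had an unadjusted p under 0.05. The differences of all of them were larger than the spread between replicates, and the count of genes that pass ran from 0 to 174 between ways of estimating that spread.

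The next genes in rank did not pass the adjusted threshold. Oxtr, the oxytocin receptor, differed by -1.2 (SE 0.12, limma adjusted p = 0.062). In the other direction, Cryl1 differed by 1.38 (SE 0.13, limma adjusted p = 0.062), the synaptotagmin Syt10 by 1.2, the phosphodiesterase subunit Pde6a by 1.71 and the p53-regulated kinase Plk2 by 1.28, the last 3 at a limma adjusted p of 0.071. Txnip, a glucose-induced inhibitor of thioredoxin, differed by 1.04 (SE 0.12), Plekhg6 by 0.99, the guidance receptor Robo1 by 0.95, the hormone secretin (Sct) by 0.96 and the copper transporter Atp7a by 0.92, with limma adjusted p of 0.071 for Txnip and 0.072 for the others.

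**Figure D1:**
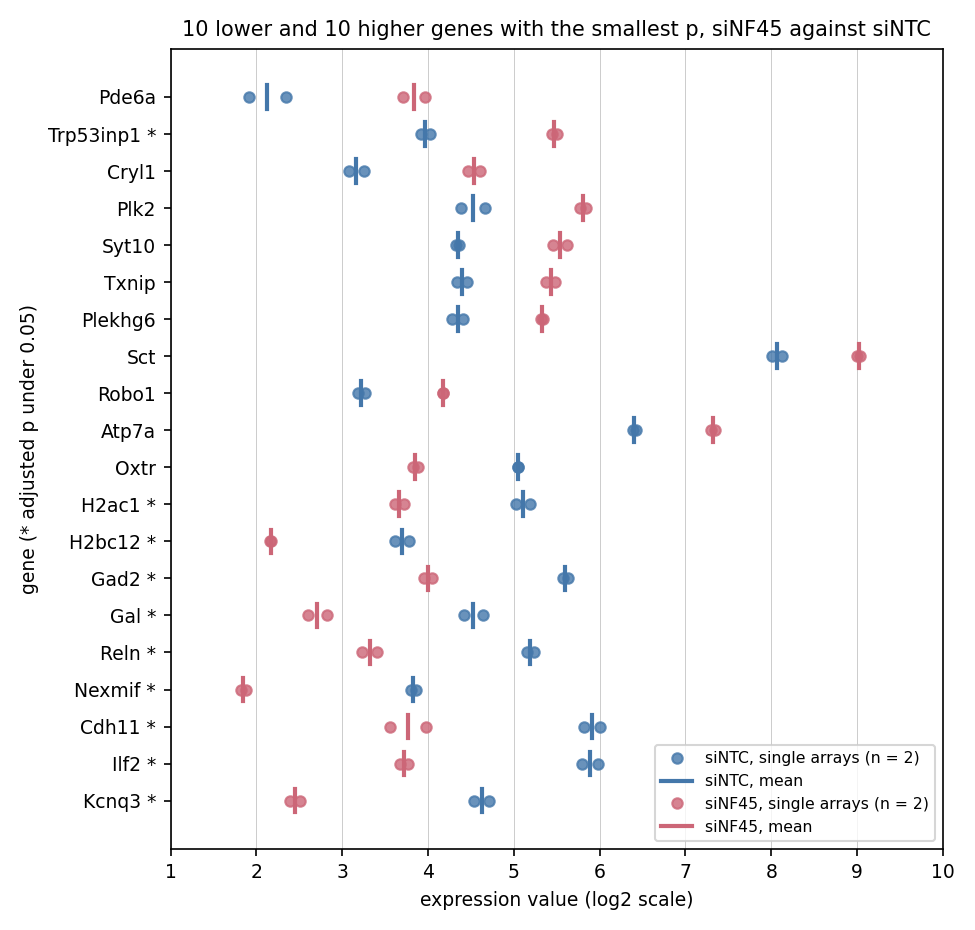
Log2 expression value (x axis) of the 10 lower and 10 higher genes with the smallest p (y axis); points are single arrays, vertical ticks are group means (n = 2 each), and an asterisk marks an adjusted p under 0.05. Ilf2 lies at 3.67 and 3.77 on the siNF45 arrays against 5.79 and 5.98 on the siNTC arrays, and Trp53inp1 is the marked gene above its controls.

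At an unadjusted p under 0.05, 2022 genes differed, where 587 would be reached by chance. Of these, 472 were higher and 1550 lower in siNF45. The median over all tested genes was -0.07, and this split moved with the scaling of the arrays. Quantile normalization gave 760 higher and 1292 lower genes around a median of -0.02. The medians of the tested genes were 3.82 and 3.76 on the siNTC arrays and 3.72 and 3.6 on the siNF45 arrays. Centring each array on that median, which adds 0.13 to the change of every gene, gave 1251 higher and 869 lower genes around a median of 0.07. The list results below compare members with the other tested genes.

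The p53 targets of the list were, as a group, higher in siNF45 than other genes. Of 24 measured members, 19 lay above 0 and the median change was 0.25. This median was 0.16 without siNTC replicate 2 and 0.38 after centring. Trp53inp1 rose over all genes and 23 members did not pass, and adjusted over the list alone 4 rose and 1 fell, which was Perp at -0.50, named after its value was seen. After Trp53inp1 and Plk2, the members with the smallest p were Mdm2, the ubiquitin ligase of p53, which differed by 0.73 (SE 0.12, limma adjusted p = 0.090), and the death receptor Tnfrsf10b by 0.72 (SE 0.13, limma adjusted p = 0.102). Cdkn1a, the p21 cell cycle inhibitor, was looked at after the values were seen and differed by 0.16 (95% interval -0.19 to 0.50). Camera gave an adjusted p of 2.35e-06. With an estimated correlation, here -0.013, and a test on 2 residual degrees of freedom, camera gave p = 0.028 and an adjusted p of 0.384.

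Genes of glycolysis and hypoxia were lower. Of 17 measured members, 15 lay below 0 and the median change was -0.55. This median was -0.32 with all probe sets of a gene averaged. None passed over all genes, where 9 were lower at an unadjusted p under 0.05, and adjusted over the list alone 8 fell. Triosephosphate isomerase (Tpi1) differed by -0.91 (SE 0.13, limma adjusted p = 0.079), hexokinase Hk1 by -0.74 (SE 0.12), the glucose transporter Slc2a1 by -0.66 (SE 0.12) and Pgam1 by -0.70 (SE 0.13). The 8 glycolytic enzymes in the list were all below 0, with a median of -0.72, and the 9 other members had a median of -0.34. Gapdh, looked at after the values were seen, differed by -0.15 (95% interval -0.53 to 0.24). Camera gave an adjusted p of 1.22e-04. With an estimated correlation, here -0.0411, and a test on 2 residual degrees of freedom, camera gave p = 0.043 and an adjusted p of 0.384.

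The cell cycle lists differed in their results. DNA replication and G1/S genes were lower than other genes, with 24 of 27 members below 0, a median of -0.17 and a camera adjusted p of 0.043, which became 0.714 as an adjusted p with an estimated correlation. None of the 27 passed over all genes or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. E2f2 differed by -0.48 (SE 0.13), Ccne1, which encodes cyclin E, by -0.55 (SE 0.18), Uhrf1 by -0.54 (SE 0.18) and E2f1 by -0.40 (SE 0.14). The call was lost after quantile normalization (adjusted p = 0.076) and after centring (0.092), without siNTC replicate 2 (0.12) and without siNF45 replicate 2 (0.089). The median was -0.04 after centring and -0.26 without siNF45 replicate 1. The mitotic G2/M list had a median of -0.07, the same as all genes, and a camera adjusted p of 0.847, with its direction turned by quantile normalization and by centring. Its leading member was Birc5, which encodes survivin, at -0.72 (SE 0.16, limma adjusted p = 0.135), followed by Nusap1 at 0.38, Cenpe at -0.27 and Anln at -0.20. No member passed over all genes or adjusted over the list alone. Whether the G1/S and G2/M lists differ from each other was not tested. Among 17 histone genes the median was -0.24 and the camera adjusted p 0.087, which was 0.040 at the 70th percentile filter, 0.046 by fry and 0.047 without siNTC replicate 1. H2bc12 and H2ac1 fell, and adjusted over the list alone 4 fell. Linker histone H1f2 differed by -0.90 (SE 0.18) and H1f10 by -0.47 (SE 0.12).

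Genes of beta cell identity and insulin secretion did not shift as a group. Of 25 members 12 lay above 0 and 13 below, with a median of -0.02, a mean of -0.05 and a camera adjusted p of 0.431 (direction up relative to the other tested genes). No member passed over all genes, Chgb fell adjusted over the list alone, and at an unadjusted p under 0.05 there were 3 higher and 5 lower. The secretory granule protein Chgb differed by -0.77 (SE 0.14, limma adjusted p = 0.105), the KATP channel pore Kcnj11 by -1.02 (SE 0.23, limma adjusted p = 0.134), the islet transcription factor Rfx6 by 0.60 (SE 0.15) and the prohormone convertase Pcsk1 by -0.44 (SE 0.12). The following genes were chosen after their values were seen. Ins2 differed by 0.18 (95% interval -0.21 to 0.56), Pdx1 by -0.05 (-0.34 to 0.25), Mafa by -0.02 (-0.30 to 0.27), Nkx6-1 by -0.02 (-0.31 to 0.28) and Iapp by -0.05 (-0.34 to 0.24). Among markers of other islet cells, somatostatin (Sst), at 9.01 ± 0.25 in siNTC (SD, n = 2), differed by -0.89 (SE 0.16, limma adjusted p = 0.103), Irx1 by -0.55, Irx2 by -0.39 and Ppy by 0.52. The 7 measured markers had a median of -0.07 and a camera adjusted p of 0.431, and adjusted over the list alone 2 fell.

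Of the 24 markers of exocrine, duct, endothelial, immune and mesenchymal cells, 4 reached the signal filter, too few for a list test. They were Krt7, which differed by 0.67 (SE 0.14, limma adjusted p = 0.132), Vim by -0.28, Col1a2 by -0.19 and Cd68 by -0.16. Their median was -0.18 and their mean 0.01. Adjusted over the list alone, 1 rose, Krt7. Interferon-stimulated genes went both ways around a median of -0.19 over 12 members, with a camera adjusted p of 0.792. Cmpk2 differed by -0.80 (SE 0.14), Ifit2 by 1.11 (SE 0.23), Stat2 by -0.47 and Irf9 by 0.19, none passed over all genes, and adjusted over the list alone 1 rose and 2 fell.

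**Figure D2:**
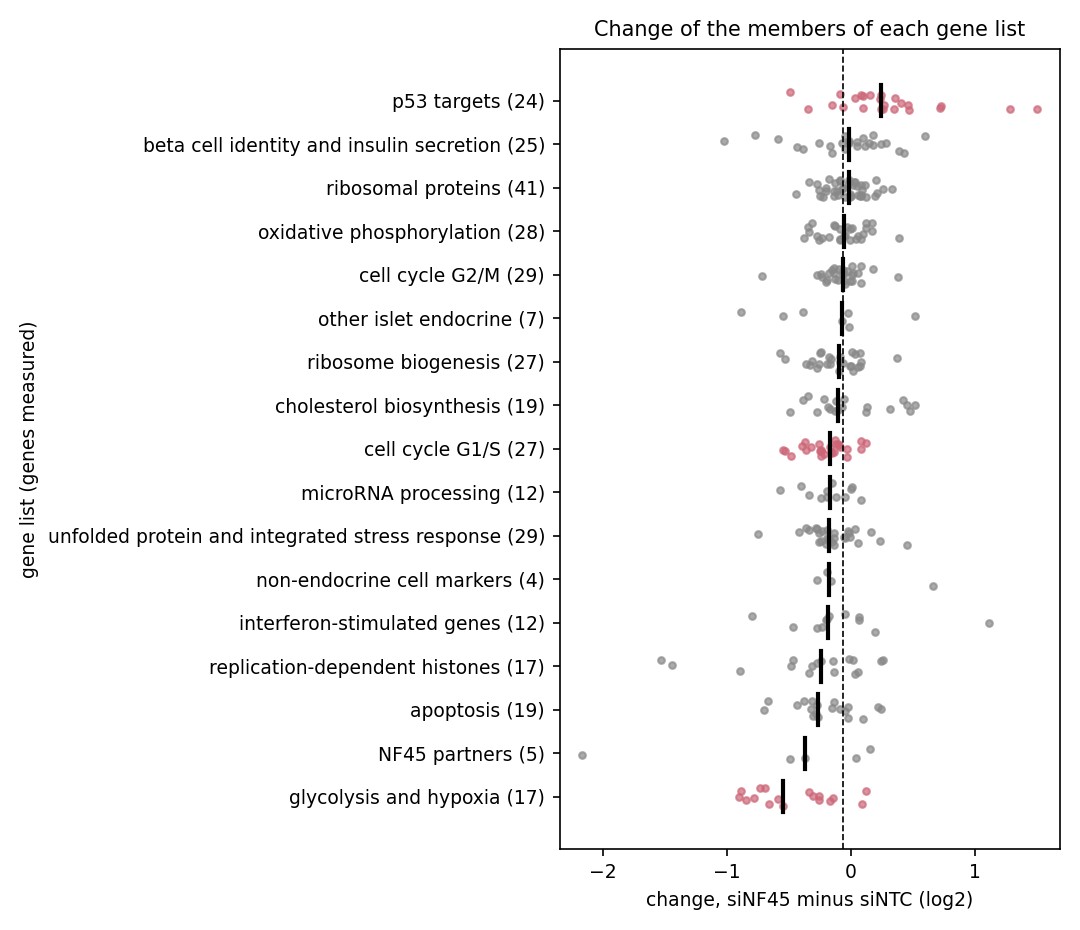
Change of each measured member (points, log2, x axis) for 17 gene lists (y axis), with the list median as a black tick and the median of all tested genes, -0.07, as a dashed line; red lists had a camera adjusted p under 0.05 at the preset correlation. The p53 targets have a median of 0.25 and the glycolysis and hypoxia genes one of -0.55.

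The RNA processing lists were not called in the fit as designed. The 12 microRNA processing genes had a median of -0.17 and a camera adjusted p of 0.274, with Drosha, the nuclear microRNA-processing nuclease, at -0.58 (SE 0.13, limma adjusted p = 0.134), the helicase Ddx17 at -0.41, Tarbp2 at -0.34 and Ran at -0.20. The 170 microRNA genes had a median of -0.08 and a camera adjusted p of 0.847. No microRNA gene passed over all genes, and adjusted over the list alone 3 fell. The members with the smallest p were Mir325 at -1.08 (SE 0.12), Mir540 at -1.10 (SE 0.13), Mir300 at -0.87 (SE 0.12) and Mir337 at -0.78 (SE 0.16). These probe sets cannot be told to measure the precursor or the mature microRNA. The 70 small nucleolar RNAs had a median of -0.18 and a camera adjusted p of 0.087, or 7.19e-04 without a filter, with Snord83b at -0.73, Snora73a at -0.76, Snora68 at -0.69 and Snora28 at 1.13, and no member passed. For ribosome biogenesis the median was -0.10 over 27 genes (camera adjusted p = 0.431), with the polymerase I factor Rrn3 at -0.58 (SE 0.12), Rrp1b at -0.54, Utp4 at 0.37 and Gnl3 at -0.32. The 41 ribosomal protein genes had a median of -0.02 (camera adjusted p = 0.469), with Rpl29 at 0.33, Rplp1 at -0.28, Rpl17 at -0.45 and Rpl14 at -0.26. Other probe sets of Rpl29 and Rplp1 went the opposite way, at -0.20 and 0.42, and signal from processed pseudogenes was not separated here.

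The lists of stress response, apoptosis, oxidative phosphorylation and cholesterol biosynthesis gave no call in that fit either. The unfolded protein and integrated stress response list had 24 of 29 members below 0, a median of -0.18 and a camera adjusted p of 0.274. Its members with the smallest p were Ppp1r15a at -0.75 (SE 0.13, limma adjusted p = 0.097), Atf3 at 0.45, Vldlr at -0.42 and Sdf2l1 at -0.37, and adjusted over the list alone 1 fell. The apoptosis list had 16 of 19 members below 0, a median of -0.27 and a camera adjusted p of 0.225, with the survival factor Mcl1 at -0.70 (SE 0.14), Fadd at -0.38, Bik at -0.67 and Tnfrsf1a at -0.44. Oxidative phosphorylation genes had a median of -0.06 over 28 members (camera adjusted p = 0.803), with Ndufa1 at 0.39, Cox4i1 at -0.35, Atp5b at -0.28 and Cox5a at -0.38. Cholesterol biosynthesis genes had a median of -0.11 over 19 members (camera adjusted p = 0.431), with Fdft1 at 0.48, Hmgcs1 at -0.50, Nsdhl at 0.52 and Pmvk at -0.39. The NF45 list of 5 genes, which holds the knocked-down Ilf2 itself, had a camera adjusted p of 0.178, and Ilf2 and Dhx9 fell adjusted over the list alone. Camera, which compares a list with the other tested genes, gave the direction up to the lists of oxidative phosphorylation, ribosomal proteins and cholesterol biosynthesis, whose medians and means were below 0.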

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

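The counts at an unadjusted p under 0.05 and the list settings without 2 members were chosen after the data were seen. With 2 arrays per group, the number of calls depended on how the spread was estimated, while the 10 called genes kept their direction in each fit. The 10 genes called as deposited remained called at the 70th percentile filter (87 genes, 17 higher and 70 lower), after quantile normalization (62, 18 and 44), after centring the arrays on the median of the tested genes (172, 71 and 101), with a trend in eBayes (174, 40 and 134), with robust eBayes and with probe sets averaged; without a filter 9 of them did. At an adjusted p under 0.10 there were 190 genes, 30 higher and 160 lower. An unmoderated per-gene test gave 324 genes at an unadjusted p under 0.05 and 1.5-fold, 58 higher and 266 lower, and 0 after Benjamini-Hochberg adjustment. Whether replicates of the same number were handled together is not known. Their deviations from the group means correlated at 0.0062 between the groups over genes. This shows no strong effect shared across genes, but with 2 arrays per group it cannot settle pairing. A fit with the replicate block called 0 genes, 0 higher and 0 lower, with Ilf2 at -2.17 and a limma adjusted p of 0.258. In that fit 1909 genes had an unadjusted p under 0.05, and it has fewer residual degrees of freedom. Leaving out each array gave 0 genes in all 4 fits (0 higher, 0 lower), in which the lone array of a group is assumed to vary like the other group, with 1236 to 1670 genes at an unadjusted p under 0.05, of which 250 to 402 were higher and 834 to 1376 lower; Ilf2 ranged from -2.26 to -2.07, with limma adjusted p from 0.307 to 0.471. Genes higher at an unadjusted p under 0.05 numbered 936 without a filter, 760 after quantile normalization and 1251 after centring, where 869 were lower. Of 1063 alternative values of the other 90 named genes, 1062 kept their direction; Rplp1 turned to 0.07 when its probe sets were averaged.

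Called lists numbered 3 as deposited and 9 without a filter. Dim genes then join the comparison, and the median of all genes goes from -0.065 to -0.005. Fry called 5 lists, and camera with an estimated correlation called 0. Both that correlation and the test then rest on 2 residual degrees of freedom. The estimate was -0.013 for p53 targets and -0.0411 for glycolysis and hypoxia, both below the preset 0.01. The higher p-values of these 2 lists thus came with the fewer degrees of freedom, not with a higher correlation. Camera with an estimated correlation gave adjusted p of 0.384 for p53 targets and for glycolysis and hypoxia and 0.714 for G1/S. The estimate for G1/S was 0.0636, above the preset. The p53 and glycolysis lists passed under all other settings run, from 6.23e-07 to 0.032 and from 1.60e-06 to 0.032. Their medians ranged over all settings from 0.16 to 0.38 and from -0.67 to -0.32, and that of the G1/S list from -0.26 to -0.04. The G1/S list missed the threshold at the 70th percentile filter (0.070), after quantile normalization (0.076), after centring (0.092), by fry (0.147) and without its most changed member (0.051), and ranged from 0.028 to 0.12 without 1 array (0.12 without siNTC replicate 2, 0.089 without siNF45 replicate 2). Lists not called as deposited passed in 12 cases. Without a filter these were NF45 partners (0.023), the stress response (0.012), ribosome biogenesis (0.026), microRNA processing (0.038), small nucleolar RNAs (7.19e-04) and apoptosis (0.010). Small nucleolar RNAs also passed with the replicate block (0.043), histones at the 70th percentile filter (0.040), without siNTC replicate 1 (0.047) and by fry (0.046), and NF45 partners (0.032) and apoptosis (0.046) by fry. The NF45 list holds the knocked-down Ilf2, so its passes say nothing of the other 4 members, which were too few for a list test. Fry does not compare a list with other genes. Lists that changed direction, none of them called as deposited, were beta cell identity (adjusted p 0.915 without a filter, 0.743 by fry), oxidative phosphorylation (0.611 and 0.324), ribosomal proteins (0.976 and 0.662), cholesterol biosynthesis (0.912 by fry), microRNA genes (0.915 without a filter, 0.474 at the 70th percentile, and 0.757 without siNF45 replicate 1, in a range of 0.676 to 0.917 without 1 array) and G2/M (0.942 after quantile normalization, 0.769 after centring, 0.982 without its most changed member, and 0.541 without siNF45 replicate 1, in a range of 0.464 to 0.917). The cause of these changes was not tested.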

Other observations

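The lists of members in this part were drawn up after the leading genes had been seen, and genes already seen were left out of them. The tests of array scaling, of signal level and of cell cycle arrest were chosen after their result was seen, and the settings without the 2 largest members after the data were seen. The 6 new lists were adjusted together, and none had a p under 0.05 by camera with an estimated correlation.

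Among genes with a limma adjusted p under 0.10 were several that respond to ERK or cAMP signalling, picked after their values were seen. These were Nr4a1 at -2.11 (SE 0.29), Dusp6 at -1.25 (SE 0.19), Sik1 at -1.16 (SE 0.14), Fosb at -1.0 (SE 0.17), Irs2 at -0.97 (SE 0.14), Spry2 at -0.87 (SE 0.12), Ppargc1a at -0.85 (SE 0.13) and Dusp4 at -0.80 (SE 0.12). Of these, the 2 siNF45 arrays differed most for Nr4a1, with 4.94 ± 0.64 against 7.05 ± 0.02 in siNTC (SD, n = 2). No separate list of cAMP-responsive genes was tested. Of 25 ERK feedback and immediate-early genes not looked at before, 20 lay below 0 and the median was -0.38. They included the ERK inhibitor Spry1 at -0.69, the nuclear receptor Nr4a3 at -0.78, Etv5 at -0.59, Ier2 at -0.58 and Fos at -0.55, with Jun opposite at 0.56. The camera p was 0.00144 (adjusted p = 0.00863, and p = 0.333 with an estimated correlation). That estimate was 0.286 for this list, far above the preset 0.01. The p at the preset correlation may therefore take too little account of members that move together. The hypothesis that the members not looked at before are lower too met its prediction at the preset correlation, and a difference in handling or medium change between the dishes may give the same pattern, which was not tested.

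MicroRNA genes of the imprinted Dlk1-Dio3 region were among the lowest of the microRNA list, with Mir540, Mir300 and Mir337. The region was taken from the gene order in the GRCm38.p6 table. Its 26 other measured microRNA genes had a median of -0.25, with 21 below 0. Mir323 lay at -0.68 (SE 0.15), Mir377 at -0.76 (SE 0.17) and Mir654 at -0.90 (SE 0.27). The camera p was 0.0107 (adjusted p = 0.0214, and p = 0.104 with an estimated correlation). With the first 3 included, the 29 genes had a median of -0.30, against -0.03 for the 141 other microRNA genes, a difference that was not tested directly. The long noncoding RNA Rian of the same region differed by 0.06 (95% interval -0.25 to 0.37). No cause was tested.

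Some cadherin and ion channel genes did not pass but had a limma adjusted p under 0.10, and were picked after their values were seen. They included Pcdh7 at -1.78, Pcdh17 at -1.19, Pcdh10 at -0.99, Grid1 at -1.09, Kcnh1 at -1.0, Kcnd2 at -0.98 and Gria2 at -0.97. The hypothesis tested was that the other members of these families are lower too. The 38 other cadherin genes had a mean of 0.07 relative to all genes (95% interval over genes -0.06 to 0.19), with a camera p of 0.0995 (camera adjusted p of 0.119). The 61 other genes of the channel list had a mean of 0.0022 (-0.07 to 0.08), with a camera p of 0.686. The channel list also held Kcnq1ot1, a long noncoding RNA, at -0.405 and Scnm1, a splicing factor, at 0.26, which are not channel genes. Neither interval reaches a mean fall of 0.5 for these remaining members. Both are spreads over genes that leave out the variation between arrays, and say nothing of the families with the picked genes included.

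The first pattern weighed is the surplus of lower over higher genes, 1550 against 472 at an unadjusted p under 0.05. It did not come from 1 array, since without each array the ratio stayed between 2.07 and 4.68. Among the tested genes, which all reached the signal filter, the ratio was 1.82 to 4.70 over bins of mean signal. Without the filter 936 genes were higher and 1834 lower, a ratio of 1.96 around a median of -0.005. Genes below the filter thus added more rises than falls, and the surplus is one of the brighter genes. Quantile normalization took the ratio from 3.28 to 1.70, with 1.59 to 1.91 without 1 array. Centring gave 0.695, but it adds 1 constant to all genes, which sets the balance by itself. Array scaling therefore stays open as part of the surplus. So does a loss of many transcripts above the filter after NF45 depletion, which was not tested.

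In the 3 ways to split the 4 arrays into 2 and 2, 1 split, the real one, reached 10 genes and the highest other had 0. At an unadjusted p under 0.05 the real split had 2022 and the others 248 and 168, where 587 would be reached by chance. The other splits mix siNTC and siNF45 arrays in each group. A difference between siNTC and siNF45 then widens the spread within groups and lowers their counts. With 3 splits a share under 0.05 cannot be reached.

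The second pattern is the higher p53 target list. Without Trp53inp1 and Plk2, its 2 largest members, its median was 0.24 and the camera p 1.92e-05 at the preset correlation, while the whole list had an adjusted p of 0.384 with an estimated correlation. For a cell cycle arrest, a fall of mitotic transcripts by 0.25 was the bound set. The G2/M list had a mean of -0.015 relative to all genes (95% interval over its members -0.08 to 0.05), which does not reach that bound. This interval is a spread over genes and leaves out the variation between arrays, so it cannot exclude an arrest. The lower G1/S list leaves a smaller change in cycling open. The 20 further p53 targets had a median of -0.005, with 10 below 0. Their mean was 0.10 relative to all genes (95% interval over these genes -0.02 to 0.21), with a camera p of 0.0616 (camera adjusted p of 0.0924). That interval lies below the list's median of 0.31 relative to all genes. It too is a spread over genes, so it cannot exclude a programme of that size. Beta-TC lines carry the SV40 T antigen, which binds p53, so regulation of Trp53inp1, Plk2 and Mdm2 by other routes may contribute and stays open, as does an off-target effect of the duplexes, since 1 pool was used.

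The third pattern is the lower glycolysis and hypoxia list. Without Tpi1 and Pfkl its median went from -0.55 to -0.34, with a camera p of 2.06e-04 at the preset correlation, while the whole list had an adjusted p of 0.384 with an estimated correlation. A weaker hypoxia response is a candidate explanation. Of 18 HIF targets outside the list, 13 lay below 0, and the median was -0.38. Among those below 0 were Fam162a at -1.18, Slc16a3 at -0.92, Narf at -0.94 and Ak4 at -0.60, with Hmox1 opposite at 0.69. The camera p was 0.00597 (p = 0.191 with an estimated correlation, here 0.0788, above the preset 0.01). A difference in cell density between dishes was not tested and stays open beside an effect of NF45.

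The 8468 probe sets with several names or none that reached the filter gave 0 calls by limma at an adjusted p under 0.05, with 312 higher and 327 lower at an unadjusted p under 0.05, where 423 would be reached by chance.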
